A study of Homo sapiens with 4 samples.

How the data were processed

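Gene expression was measured by RNA-seq in SKNMC cells given CBL0137 at 1 µM or DMSO vehicle for 24 h, with 2 libraries per group. Group and replicate number were read from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made by standard Illumina methods. Whether the libraries selected polyadenylated RNA or marked the strand is not given in the sources used here.

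The deposited table holds raw read counts per gene and FPKM values for each of the 4 libraries, with Ensembl gene identifiers. Per the series' design text, the authors trimmed adapters with Trim Galore, aligned reads to hg19 with HISAT2, obtained the counts with HTSeq 0.11.1 and called differential genes with DESeq2 1.26.0 at a fold above 1.5 and a false discovery rate under 0.05. The submitters' processing notes also name mm10, a mouse genome build, without saying what it was used for. The annotation release and the strand setting of the counting are not given in the sources used here. The authors computed the FPKM values from read number, gene length and sequencing depth, per the series' design text; the tool is not given in the sources used here. The deposited FPKM values are not a rescaling of the deposited counts: 5103 genes with 0 counts in every library had an FPKM above 0, and 76 genes had the reverse. Counts were therefore the basis of the tests, and FPKM entered as an alternative.

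The table had 60617 gene entries and 6 entries that name no gene. The latter were the 5 HTSeq summary entries and a stray header line, and they stayed out of library sizes and tests. Reads counted in no annotated gene made up 8.52% and 8.82% of all counted reads in DMSO replicates 1 and 2 and 10.3% and 10.2% in CBL0137 replicates 1 and 2. Reads in overlapping genes were 9.34%, 9.27%, 8.75% and 8.78% in the same order, and reads aligned to more than 1 place were 7.13%, 7.05%, 7.13% and 6.91%. Gene positions and types came from GENCODE release 44 mapped to GRCh37, the same build as hg19, which held 58524 of the identifiers. Gene names came from a separate list, which gave 41078 of the 60617 gene entries a name of their own. SOD2, BOP1 and PECAM1, each in a gene list, matched no identifier and were not analysed here.

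Reads assigned to genes numbered 20086664 and 19625517 in the DMSO libraries and 20767817 and 21061892 in the CBL0137 libraries. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom over genes of 3.12 for DMSO and 2.82 for CBL0137, so they were kept as separate samples. Intervals on shares of reads are 95% Wilson intervals and cover counting error only. With 2 samples against 2, the smallest p that an exact two-sided permutation test of 1 value can give is 0.333, so single values outside the gene model carry no p-value.

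Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM normalization, filterByExpr filter) in R 4.3.3, which kept 17374 genes. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its fold above 1.5, the limits named in the series' design text. CPM values use TMM effective library sizes (factors 0.943 and 0.950 for DMSO, 1.06 and 1.05 for CBL0137). They are shares of the sequenced RNA, so a change in total RNA per cell would not show. SE values are the absolute log2 fold change divided by the square root of F. The common dispersion corresponded to a coefficient of variation of 4.11% between replicates.

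The groups, the test, the thresholds, 25 gene lists, the rule for naming genes and most alternatives were set before the data were examined. Lists with at least 5 tested members, 23 of them, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over these lists. FACT and the endothelial markers had too few tested members. Each list was also tested with an estimated correlation and with fry. The former has few residual degrees of freedom with 2 libraries per group, so a call lost there does not argue against a list. The rule for naming genes took the 6 called genes with the highest and the 6 with the lowest log2 fold change among those with an average log2 CPM of at least 3 and no overlap between groups, then the 2 members with the smallest p of each list (3 for the EWSR1-FLI1 lists, 0 for ribosomal proteins and the markers of other cell types), and a fixed set of genes of the fusion and its context. It named 64 genes, and the values of some of them and of some list members are not reported here. Other genes are named as members of counts or as examples, and these were chosen after their values were seen. Of the 64 genes, 43 overlap another annotated gene, 41 of them a gene on the opposite strand. As the strand setting is not stated, reads of such pairs cannot be told apart with certainty. Members of multigene families with near-identical copies, such as histone, ribosomal protein and HSPA1A or HSPA1B genes, are likewise uncertain.

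The steps were tested on simulated counts drawn from the means and library sizes of these libraries. In the simulated comparison of CBL0137 with DMSO (16902 genes), edgeR gave an adjusted p under 0.05 to 65.7% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 100% of those changed 4-fold, and to 6 of 16702 unchanged genes. These folds were given to only 67, 67 and 66 genes, whereas 10722 real genes reached an adjusted p under 0.05 with edgeR. The adjusted limit was therefore stricter in the simulation, and its percentages do not carry over to the real data. On 17374 simulated genes, camera called 1 of 1 raised list and 0 of 20 unchanged lists. Simulated genes varied independently, so this does not cover lists of correlated genes. On 16858 genes, removing a simulated GC trend took the calls from 3214 to 0.

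Alternatives were DESeq2 1.42.0, other normalizations (RLE size factors, upper quartile, library size alone), no filter on low counts, a CPM of at least 1 throughout a group, each library left out in turn, the replicate number as a block, other thresholds, and limma with trend on log2(FPKM + 1) for genes with a mean FPKM of at least 1. Chosen after seeing the data were the removal of the trend of log2 counts with GC content and gene span, the same with the replicate block, a test of protein-coding genes only, and 5 further gene lists. GC content and span were known for 99.3% of tested genes.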

Results

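SKNMC is an established human Ewing sarcoma cell line. These tumours carry a fusion of EWSR1 with an ETS transcription factor gene, most often FLI1, whose protein activates some genes and represses others. CBL0137 is a curaxin, a small molecule that binds DNA and traps the histone chaperone FACT on chromatin. RNA-seq libraries were made from cells kept for 24 h in 1 µM CBL0137 (n = 2) or in the DMSO vehicle (n = 2). The series concerns inhibition of FACT in Ewing sarcoma, and its design poses the question of which transcripts differ between treated and vehicle cells. The DMSO libraries held 20086664 and 19625517 reads assigned to genes, and the CBL0137 libraries 20767817 and 21061892. A read was seen for 25961 and 25973 genes in the DMSO libraries and for 27997 and 27887 genes in the CBL0137 libraries. No label says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

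In the integrated stress and unfolded protein response list 21 of 29 tested genes fell and 0 rose, and in the ribosomal protein list 33 of 78 fell (13 with library size alone) and 0 rose. In the hypoxia and glycolysis list 13 of 28 fell and 2 rose. Of the genes activated by EWSR1-FLI1, 26 of 55 fell and 2 rose, whereas FLI1 itself had a log2 fold change of 0.02 (SE 0.06). SSRP1, which encodes a FACT subunit, fell by 1.12 on the log2 scale (SE 0.05). Of 64 histone genes 21 were tested and 13 rose (8 with DESeq2), and of 16 epithelial markers 9 were tested and 7 rose (3 with FPKM). Camera adjusted p-values for these lists are given with each group. No list kept its call when the correlation between genes was estimated from the data, even where the estimate was under the preset 0.01. With 2 libraries per group that version of the test has few residual degrees of freedom. The lost calls therefore cannot show whether a list moved.

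Of 17374 genes tested, 5798 were called, 3166 higher and 2632 lower with CBL0137 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 and fold above 1.5). These shares over all genes are the background for the counts of calls within each list. An adjusted p under 0.05 without the fold limit was reached by 10722 genes. The first principal component separated the groups and held 85.5% of the variance. The balance between directions depended on the scaling: 54.6% of calls were higher with TMM factors, but 68.8% with library size alone (4138 higher and 1877 lower), which moved the median log2 fold change of all genes by 0.16. It also depended on the test, filter and threshold. The share was 49.9% with DESeq2 (2311 higher and 2316 lower), 50.9% with no filter on low counts, 49.9% with no fold limit and 62.0% with a fold above 2. Long non-coding RNA genes had 730 higher and 291 lower calls, against 2201 and 2143 for protein-coding genes (Fisher's exact test across genes, which are not independent replicates, p = 2.5e-34). The share of higher calls was 71.5% for lncRNA genes and 68.3% for protein-coding genes matched on abundance (middle 95% of 1000 draws 65.7 to 70.9). Both CBL0137 libraries had a larger share of uniquely aligned reads counted in no annotated gene than both DMSO libraries, with means of 11.01% ± 0.0871 and 9.34% ± 0.221 (SD, n = 2). Calls also followed GC content: 1109 genes were higher and 291 lower in the fifth of genes richest in GC, and 309 higher and 691 lower in the fifth poorest in GC.

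**Figure D1:**
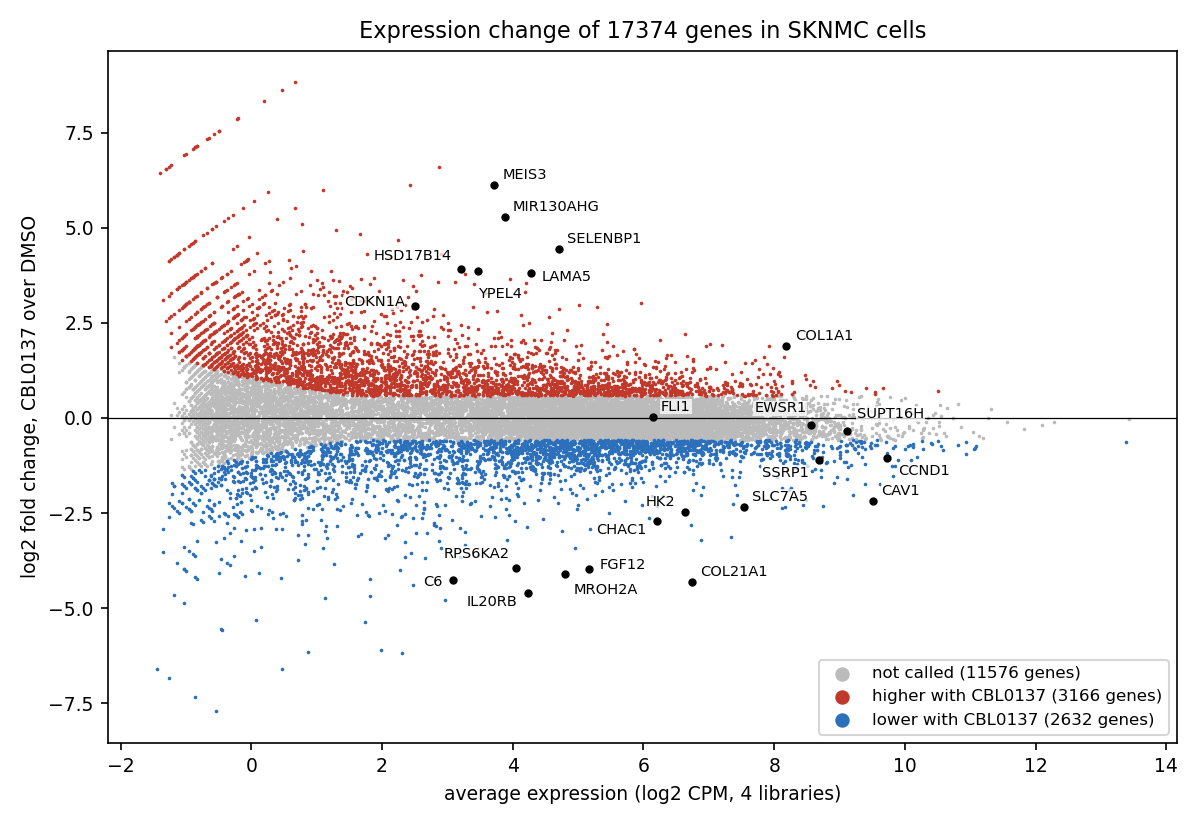
Log2 fold change (CBL0137 over DMSO, vertical axis) against average expression in log2 CPM (horizontal axis) for the 17374 tested genes, 1 point per gene, with 3166 higher calls in red, 2632 lower calls in blue and the other 11576 in grey. Black points are labelled genes, with MEIS3 (6.11) at the top and IL20RB (-4.61) at the bottom of those labelled.

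The steepest rises among genes with an average log2 CPM of at least 3 were those of MEIS3, MIR130AHG, SELENBP1, HSD17B14, YPEL4 and LAMA5. MEIS3, a homeobox gene (ENSG00000105419, GRCh37 chromosome 19, 47906381 to 47922784, minus strand), went from 0.346 ± 0.109 to 24.4 ± 0.379 CPM (SD, n = 2), a log2 fold change of 6.11 (SE 0.22, edgeR adjusted p = 1.1e-25). SELENBP1, which encodes a selenium-binding protein (ENSG00000143416, chromosome 1, 151336780 to 151345183, minus strand), went from 2.21 ± 0.0878 to 47.9 ± 0.0382 CPM, a log2 fold change of 4.43 (SE 0.13, adjusted p = 7.6e-29). LAMA5, a laminin chain gene (ENSG00000130702, chromosome 20, 60883011 to 60942368, minus strand), rose by 3.82 (SE 0.14), and HSD17B14, a hydroxysteroid dehydrogenase gene (ENSG00000087076, chromosome 19, 49316275 to 49339767, minus strand), by 3.92 (SE 0.21), and by 4.62 without DMSO replicate 1. The values of MIR130AHG (5.27) and YPEL4 (3.87) are uncertain, since these genes overlap on opposite strands of chromosome 11 (57405497 to 57420263 and 57412560 to 57417417). LAMA5 also overlaps genes on the opposite strand, ADRM1 and LAMA5-AS1. With log2(FPKM + 1) the calls stood at smaller differences: MEIS3 at 2.79, MIR130AHG at 2.65, SELENBP1 at 3.76, HSD17B14 at 2.79, YPEL4 at 2.34 and LAMA5 at 1.59. The added 1 draws such differences toward 0 for genes with low FPKM, so they need not mean smaller changes.

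COL21A1, a collagen gene (ENSG00000124749, chromosome 6, 55921388 to 56258892, minus strand), fell from 207 ± 6.61 to 10.3 ± 0.153 CPM (SD, n = 2), a log2 fold change of -4.32 (SE 0.07, edgeR adjusted p = 9.3e-37). IL20RB, a cytokine receptor subunit gene (ENSG00000174564, chromosome 3, 136665072 to 136729927, plus strand), fell from 37.7 ± 3.83 to 1.54 ± 0.184 CPM, a log2 fold change of -4.61 (SE 0.15, adjusted p = 2.9e-27). FGF12, of the fibroblast growth factor family (ENSG00000114279, chromosome 3, 191857179 to 192485553, minus strand), had a log2 fold change of -3.98 (SE 0.10). The other 3 were the complement gene C6 (-4.25, SE 0.21), MROH2A (-4.09, SE 0.12) and the ribosomal S6 kinase gene RPS6KA2 (-3.95, SE 0.14). Apart from C6, all of these genes overlap other annotated genes, so their reads are uncertain too. IL20RB, for example, overlaps NCK1 on the same strand, and MROH2A overlaps HJURP on the opposite strand. With FPKM, COL21A1 was at -3.13, IL20RB at -3.005, FGF12 at -0.66, C6 at -1.78, MROH2A at -2.05 and RPS6KA2 at -2.18, all still called. The naming rule required both CBL0137 libraries of each of these 12 genes to lie on the same side of both DMSO libraries. That separation therefore adds no support for the changes.

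SSRP1 and SUPT16H encode the subunits of FACT. SSRP1 (ENSG00000149136, chromosome 11, 57093460 to 57103366, minus strand) fell from 566 ± 19.5 to 261 ± 8.16 CPM (SD, n = 2), with a log2 fold change of -1.12 (SE 0.05, edgeR adjusted p = 1.5e-21). SUPT16H (ENSG00000092201, chromosome 14, 21819635 to 21852178, minus strand) was at 616 ± 10.95 and 488 ± 29.8 CPM, a log2 fold change of -0.33 (SE 0.05, adjusted p = 7.3e-07) that stayed under the fold limit. EWSR1 (ENSG00000182944, chromosome 22, 29663998 to 29696515, plus strand) was at 400.1 ± 0.190 and 353 ± 5.54 CPM, a log2 fold change of -0.18 (SE 0.05, adjusted p = 0.0023). FLI1 (ENSG00000151702, chromosome 11, 128556430 to 128683162, plus strand) was at 69.9 ± 0.759 and 71.1 ± 2.18 CPM (log2 fold change 0.02, SE 0.06, adjusted p = 0.766), and its sign turned without DMSO replicate 1 (-0.0049) or without CBL0137 replicate 1 (-0.01). Counts per gene do not separate a fusion transcript from those of the unfused alleles.

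Genes activated by EWSR1-FLI1 fell as a set: of 55 tested, 26 fell, 2 rose (4 with library size alone) and 27 were not called (median log2 fold change -0.53, camera adjusted p = 6.3e-05, and adjusted p = 0.429 with an estimated correlation). CCK, which encodes cholecystokinin, fell from 467 ± 11.1 to 89.7 ± 0.374 CPM (SD, n = 2), a log2 fold change of -2.38. CAV1, the gene of caveolin, fell from 1198 ± 6.83 to 264 ± 14.9 CPM (-2.18), and FCGRT, the gene of the neonatal Fc receptor, from 1031 ± 52.1 to 310 ± 14.3 CPM (-1.74). The cyclin gene CCND1 fell by 1.06 (SE 0.05) and MYC by 0.74 (SE 0.05). NR0B1, a nuclear receptor gene, fell by 0.67 (SE 0.06), a call lost without CBL0137 replicate 1 (-0.57), with library size alone (-0.51) and with FPKM (-0.53). GLI1 (-0.30, SE 0.07) and NKX2-2 (0.23, SE 0.08) did not pass, and NKX2-2 was at -0.04 once the GC and span trend was removed. The 2 that rose were REPS2 (3.16) and ADGRG2 (0.96).

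Genes repressed by EWSR1-FLI1 went both ways, with 6 of 28 higher, 6 lower and 16 not called (median -0.12, mean 0.08, camera adjusted p = 0.852, and median 0.04 with library size alone). IGFBP5, which encodes an insulin-like growth factor binding protein, rose from 152 ± 4.79 to 337 ± 15.5 CPM (SD, n = 2), a log2 fold change of 1.14. The vinculin gene VCL rose by 0.93 (SE 0.06). The receptor tyrosine kinase gene MET fell from 115 ± 2.44 to 27.6 ± 2.17 CPM, a log2 fold change of -2.06.

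**Figure D2:**
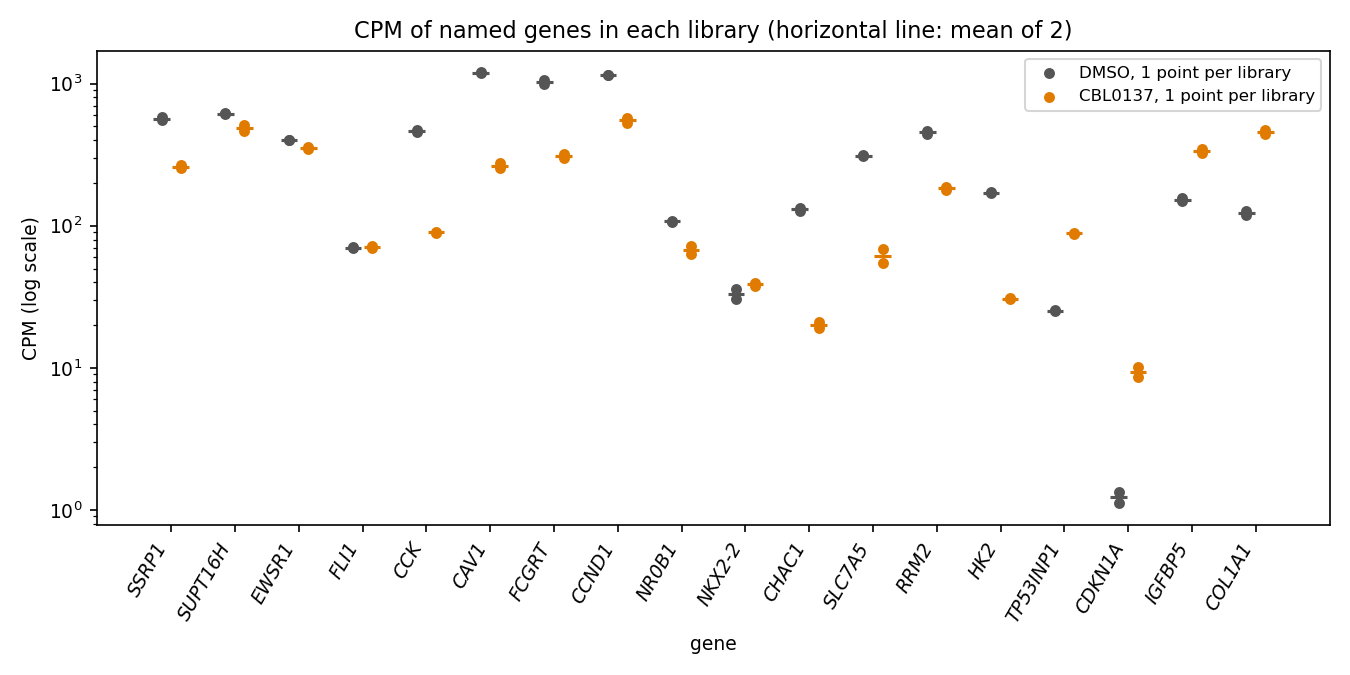
CPM on a log scale (vertical axis) of 18 named genes (horizontal axis) in DMSO libraries (grey) and CBL0137 libraries (orange), 1 point per library, with a line at the mean of 2. CAV1 lies at 1198 CPM with DMSO and 264 CPM with CBL0137, while the FLI1 means lie at 69.9 and 71.1 CPM.

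Genes of the integrated stress and unfolded protein response had the lowest median of the 23 tested lists that were set before the data were examined, with 21 of 29 lower, 0 higher (1 with library size alone) and 8 not called (median -1.01, camera adjusted p = 1.9e-07, and adjusted p = 0.429 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, fell from 130 ± 4.62 to 19.9 ± 1.40 CPM (SD, n = 2), a log2 fold change of -2.71 (SE 0.07, edgeR adjusted p = 2.7e-30). SLC7A5, the gene of a large neutral amino acid transporter, fell from 312 ± 1.95 to 61.6 ± 9.47 CPM (-2.34, SE 0.07). Among other members, the serine synthesis gene PSAT1 (-2.19), the asparagine synthetase gene ASNS (-1.78, and -3.06 with FPKM) and the transcription factor gene ATF4 (-0.80) fell. The endoplasmic reticulum chaperone gene HSPA5 fell by 0.72, a call lost without DMSO replicate 1 (-0.42), with library size alone (-0.56) and with FPKM (-0.57), and XBP1 (-0.27) and DDIT3 (-0.07) were not called.

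Ribosomal protein genes showed 33 of 78 lower, 0 higher and 45 not called (median -0.52, camera adjusted p = 5.7e-12, and adjusted p = 0.578 with an estimated correlation). Their median stayed below 0 in each scaling tried and was -0.36 with library size alone, where 13 were called lower, against 20 with FPKM. RPL9 fell by 1.24 (not called with FPKM, at -0.45) and RPL36A by 1.62, while RPS26 was at 0.19. The MYC target and ribosome biogenesis genes had 15 of 38 lower, 0 higher and 23 not called (median -0.50, camera adjusted p = 1.9e-07, and adjusted p = 0.429 with an estimated correlation), with 8 lower under library size alone. SRM, the spermidine synthase gene, fell from 94.4 ± 2.80 to 31.6 ± 0.173 CPM (SD, n = 2), a log2 fold change of -1.58, and the nucleolar GTPase gene GNL3 fell by 1.11 (SE 0.06).

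Hypoxia and glycolysis genes had 13 of 28 lower, 2 higher (4 with upper-quartile factors, library size alone or FPKM) and 13 not called (median -0.49, camera adjusted p = 0.0032, and adjusted p = 0.429 with an estimated correlation). The hexokinase gene HK2 fell from 171 ± 2.97 to 30.7 ± 0.216 CPM (SD, n = 2), a log2 fold change of -2.47 (SE 0.06, edgeR adjusted p = 1.1e-30), and the enolase gene ENO1 from 2575 ± 36.4 to 1335 ± 58.8 CPM (-0.95). The glucose transporter gene SLC2A3 fell by 1.70 (1.11 with FPKM) and the lactate dehydrogenase gene LDHA by 0.79. The members that rose were NDRG1 (1.55) and ADM (1.43). In the list of insulin-like growth factor signalling, 7 of 23 fell and 2 rose (median -0.15, camera adjusted p = 0.303). With library size alone 5 fell and 5 rose (median 0.01), with upper-quartile factors 7 and 5, with FPKM 4 and 2, and without CBL0137 replicate 2 7 and 4. The adaptor genes IRS1 (-1.57, SE 0.07) and IRS2 (-1.16, SE 0.05) fell, IGF1R was at -0.33 (SE 0.06) under the fold limit, and IGFBP5 (1.14) and IGFBP3 (3.48) rose. Cholesterol synthesis genes had 4 of 25 higher and 3 lower (1 with FPKM; median 0.15, camera adjusted p = 0.281). The sterol reductase gene TM7SF2 (1.75, SE 0.08) was among those that rose, with HSD17B7 (0.78), and PMVK (-0.76) was among those that fell.

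Genes of DNA replication and the G1/S step had 13 of 45 lower, 0 higher and 32 not called (median -0.29, camera adjusted p = 0.00019, and adjusted p = 0.429 with an estimated correlation). RRM2, a ribonucleotide reductase subunit gene, fell from 454 ± 19.6 to 183 ± 5.40 CPM (SD, n = 2), a log2 fold change of -1.31, and the checkpoint gene CLSPN fell by 1.05 (SE 0.06). Of the DNA damage repair and checkpoint genes, 8 of 44 fell, 2 rose and 34 were not called (median -0.29, camera adjusted p = 0.0021, and adjusted p = 0.429 with an estimated correlation). Over all 17374 tested genes 2632 were called lower and 3166 higher. The share of lower calls in this list was thus near that of all genes, as it was for the G2/M list below. The end resection gene RBBP8 fell by 1.49 (SE 0.06) and NBN, of the complex that senses DNA breaks, by 1.19 (SE 0.06), while POLQ (1.00) and LIG4 (0.76), both of end joining, rose. This list lost its call once the trend with GC content and gene span was removed (median -0.25, 5 lower, adjusted p = 0.259), and 3 members were called lower with library size alone and 4 with FPKM. G2/M and mitosis genes had 6 of 46 lower and 2 higher (median -0.13, camera adjusted p = 0.114), with an adjusted p of 0.0299 without DMSO replicate 1 and a median of 0.03 with library size alone, and FPKM gave 3 lower and 1 higher. CCNA2, a cyclin gene, fell by 0.93 (SE 0.06), and the spindle gene ASPM (0.98, SE 0.06) rose. PRC1 (0.72) was called higher, but not without DMSO replicate 2 (0.21) or CBL0137 replicate 2 (0.57), with DESeq2 (0.71), with no filter on low counts (0.70) or with FPKM (-0.21), and it was at 1.47 without DMSO replicate 1.

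Replication-dependent histone genes, whose mRNAs mostly end without a poly(A) tail, had 13 of 21 higher, 2 lower and 6 not called (median 1.02, camera adjusted p = 0.0036, and adjusted p = 0.429 with an estimated correlation). H2AC11 rose from 2.75 ± 0.521 to 10.1 ± 0.0554 CPM (SD, n = 2), a log2 fold change of 1.88 (SE 0.19, and 1.21 with FPKM), and H2AC25 from 0.347 ± 0.192 to 4.24 ± 1.59 CPM (3.59, SE 0.40, and 4.27 without DMSO replicate 2 and 1.81 with FPKM). DESeq2 called 8 higher and 0 lower and FPKM 7 higher and 1 lower. The lower calls were those of H1-4 (-1.60) and H2AC20 (-0.76), of which 0 were made without DMSO replicate 1 and 1 without each of the other libraries, with no filter on low counts or with the stricter one. These genes stood at low levels and some have near-identical copies, so their single values are uncertain. Of 64 genes in the list only 21 passed the low-count filter, which a gene low with DMSO could pass through the CBL0137 libraries alone. An excess of higher calls (68.3%) was also seen in protein-coding genes matched to the abundance of lncRNA genes.

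The p53 target list had 7 of 32 higher and 7 lower (4 lower with FPKM; median -0.02, camera adjusted p = 0.713). The median was 0.14 with library size alone, 0.05 with upper-quartile factors or FPKM and 0.01 with the GC and span trend removed. CDKN1A, the gene of the p21 cyclin-dependent kinase inhibitor, rose from 1.23 ± 0.165 to 9.39 ± 1.08 CPM (SD, n = 2), a log2 fold change of 2.93 (SE 0.23, edgeR adjusted p = 1.2e-14, and 1.60 with FPKM), and TP53INP1 rose by 1.81 (SE 0.07). PMAIP1, the gene of the BH3-only protein NOXA, fell from 114 ± 1.07 to 33.1 ± 4.88 CPM (-1.79, SE 0.07). Among apoptosis-promoting genes, 5 of 23 were higher and 4 lower (median 0.02, camera adjusted p = 0.922, with the test's direction opposite to that of the median). BMF (1.62, SE 0.06), TNFRSF10A (1.67), DIABLO (1.00), BBC3 (0.95) and CASP9 (0.80) rose, and PMAIP1 (-1.79), CASP10 (-1.76), CYCS (-0.96) and BID (-0.77) fell. DESeq2 called 3 higher, without BBC3 (adjusted p = 0.061) and TNFRSF10A (0.051), and BBC3 was at 0.44 and not called with the GC and span trend removed. FPKM gave 1 higher and 3 lower, with DIABLO at -0.12 and CASP9 at 0.55, and the median was -0.04 without DMSO replicate 1, -0.01 without CBL0137 replicate 2 and -0.0047 with no filter on low counts. Of 10 apoptosis-inhibiting genes 0 were called higher and 1, BIRC3 (-0.72), was called lower (median -0.23, camera adjusted p = 0.574). BIRC3 was not called with upper-quartile factors (-0.65), library size alone (-0.56), DESeq2 (-0.74), no filter on low counts (-0.74) or the trend removed (-0.53), nor without DMSO replicate 1 (-0.66) or CBL0137 replicate 2 (-0.38), and FPKM gave 0 lower calls in this list. CFLAR (0.56, SE 0.06) and BCL2 (-0.54, SE 0.07) were just under the fold limit. CFLAR passed with upper-quartile factors (0.63), library size alone (0.72) and the GC and span trend removed (0.65), and BCL2 was at -0.59 without DMSO replicate 1, past the fold limit. With the trend removed BIRC6 (0.59) and BCL2L1 (-0.61) also passed, which gave 2 higher and 1 lower calls in this list.

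Interferon-stimulated genes split, with 8 of 33 higher and 15 lower (median -0.26, camera adjusted p = 0.585), and with FPKM 6 were higher and 3 lower (median 0.18). STAT2, a transcription factor gene of the interferon response, rose by 1.04 (SE 0.06), and OAS3, an oligoadenylate synthetase gene, fell by 1.70 (SE 0.10, and 1.06 with FPKM). Of the NF-kappaB target genes, 3 of 15 were higher and 3 lower (median -0.23, mean 0.38, camera adjusted p = 0.280), and 0 were called with FPKM. ICAM1, a cell adhesion gene, had 0 and 1 reads in the DMSO libraries and 26 and 40 in the CBL0137 libraries, a ratio of 56.2 after TMM scaling. The exact 95% interval of 9.73 to 2251 covers counting error only and not the spread between samples. The fitted log2 fold change was 4.64 without DMSO replicate 1 and 7.97 without DMSO replicate 2, which leaves 0 DMSO reads for this gene, so the latter depends on the prior count and is no bound. TNFAIP2 (2.74) and CSF1 (3.19, and 2.60 without DMSO replicate 1 and 4.11 without DMSO replicate 2) were also higher, and PTGS2 (-1.88, SE 0.31) and RELB (-1.29) fell, beside the call of BIRC3 that some other settings did not make. Heat shock genes had 6 of 26 higher and 0 lower (median 0.15, camera adjusted p = 0.105, and 0.0263 with library size alone). HSPH1 rose by 0.84 (SE 0.05) and HSPB1 by 1.02 (SE 0.06), the latter at 0.54 and under the fold limit once the GC and span trend was removed. Immediate early genes had 9 of 24 higher and 4 lower (median 0.06, camera adjusted p = 0.574, and median -0.05 without CBL0137 replicate 1), with JUNB (1.22, SE 0.10) higher and MYC (-0.74), FOSL2 (-0.88), EGR2 (-0.82) and KLF6 (-0.77) lower. FPKM gave 5 higher and 1 lower, with EGR2 at -0.37 and KLF6 at -0.55.

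Neuronal genes had 6 of 20 lower and 2 higher (median -0.26, camera adjusted p = 0.114, and 0.0481 without CBL0137 replicate 1), and 4 lower and 0 higher with FPKM. SCG2, the secretogranin gene, fell from 15.8 ± 0.611 to 0.566 ± 0.157 CPM (SD, n = 2), a log2 fold change of -4.79 (SE 0.23, and -2.19 with FPKM), the microtubule gene MAPT fell by 0.80 (SE 0.05), and KIF5C (3.25) and PRPH (2.04) rose. PRPH was at 2.86 without DMSO replicate 1, and KIF5C at 2.27 without DMSO replicate 2 and at 7.78 without DMSO replicate 1, which leaves it 0 DMSO reads, so that this value depends on the prior count and is no bound. Extracellular matrix and mesenchymal genes had 7 of 32 higher and 11 lower (median -0.31, camera adjusted p = 0.280). The collagen gene COL1A1 rose from 123 ± 5.60 to 456 ± 20.97 CPM, a log2 fold change of 1.89 (SE 0.06), and the tenascin gene TNC fell from 54.3 ± 0.506 to 11.02 ± 0.702 CPM (-2.30, SE 0.09, and -1.40 with FPKM).

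Lists of markers of other cell types were included as a check for RNA of other cells. Of 16 epithelial markers only 9 passed the low-count filter, and a gene near 0 with DMSO, such as GRHL2, could pass through the CBL0137 libraries alone. Epithelial markers had 7 of 9 higher, 1 lower and 1 not called (median 1.42, camera adjusted p = 0.0221, and adjusted p = 0.429 with an estimated correlation), and the call was lost with library size alone (adjusted p = 0.0623), while FPKM gave 3 higher. GRHL2, an epithelial transcription factor gene, went from 0.133 ± 0.0392 to 13.5 ± 2.49 CPM (SD, n = 2), EPCAM from 2.85 ± 0.372 to 7.62 ± 0.664 CPM and the keratin gene KRT18 from 46.2 ± 0.565 to 98.3 ± 1.40 CPM, while the splicing regulator gene ESRP1 fell from 119 ± 15.1 to 19.1 ± 2.62 CPM (a log2 fold change of -2.63, and -1.82 with FPKM). Of 5 tested blood cell markers CD4 (1.05) and CD8A (1.98) were called higher (median 0.24, camera adjusted p = 0.713, and median -0.32 with FPKM and -0.02 with the stricter filter). CD8A was not called with DESeq2 (adjusted p = 0.231), with no filter on low counts (0.107), without DMSO replicate 1 (1.30 on the log2 scale) or without CBL0137 replicate 1 (1.97) or 2 (1.98), and was at 3.21 without DMSO replicate 2. PTPRC was at 162 ± 0.299 CPM with DMSO and 115 ± 11.9 CPM with CBL0137, and was called lower without CBL0137 replicate 2 (-0.61) and with FPKM (-0.65). Of 3 tested endothelial markers CDH5 (1.05) was called higher, but not with DESeq2 (adjusted p = 0.0634), and EMCN (-0.76) lower, but not with FPKM (-0.31) or the GC and span trend removed (-0.32).

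**Figure D3:**
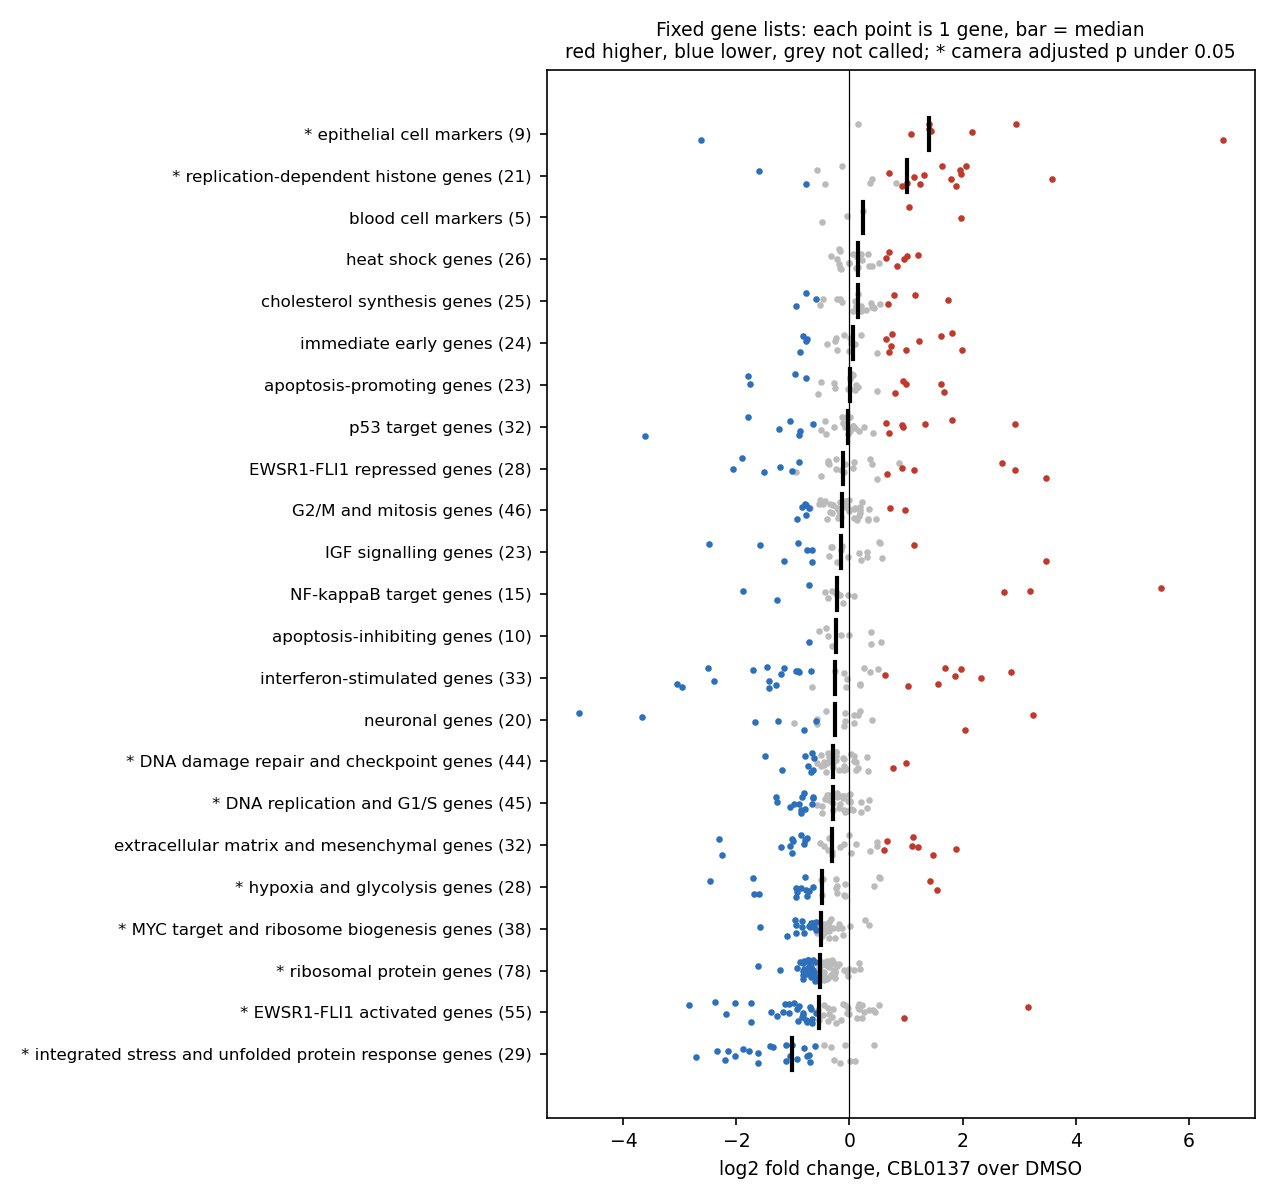
Log2 fold change (CBL0137 over DMSO, horizontal axis) of each tested gene of the 23 fixed lists (vertical axis, number of genes in brackets), 1 point per gene in red (higher), blue (lower) or grey (not called), with a bar at the median and a star where the camera adjusted p is under 0.05. Medians run from 1.42 for epithelial markers to -1.01 for the integrated stress and unfolded protein response genes, and 9 lists carry a star.

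Of the 23 lists tested with camera at a preset correlation of 0.01, 9 were called, and with an estimated correlation 0 were called (1 list, DNA replication and G1/S, at an unadjusted p under 0.05), while fry, which asks whether a list's genes move 1 way on balance, called 15. The estimated correlation was under 0.01 for the replication (-0.0104), repair (-0.0059), histone (-0.033) and epithelial (-0.069) lists, which lost their calls too. A larger correlation cannot explain that loss. With 2 libraries per group this test has few residual degrees of freedom, so the loss does not argue against these lists. In the replication list the unadjusted camera p was 4.0e-05 with the preset correlation and 0.0388 with the estimate. For the other called lists the estimate ran from 0.023 (hypoxia and glycolysis) to 0.627 (ribosomal proteins). Counts adjusted over the list alone equalled those over all genes tested in every list. The comparison rests on 2 libraries per group, and values are relative to the sequenced RNA of each library.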

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

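The tests in this part were set before their values were seen, except the margin applied to the comparison of lncRNA genes with matched protein-coding genes and the count of olfactory receptor genes without a read and the pairings of their libraries, which were chosen after the result was seen. Data outside the gene counts showed a difference: the share of uniquely aligned reads counted in no annotated gene was 11.01% ± 0.0871 in the CBL0137 libraries and 9.34% ± 0.221 in the DMSO libraries (SD, n = 2). By library it was 9.18% (95% Wilson interval 9.17 to 9.19) and 9.49% (9.48 to 9.50) with DMSO and 11.07% (11.06 to 11.08) and 10.95% (10.93 to 10.96) with CBL0137, and the intervals cover counting error only. With 2 against 2 samples an exact two-sided permutation test cannot give a p below 0.333. Annotated lncRNA genes took 1.63% ± 0.0135 of gene reads with CBL0137 and 1.37% ± 0.0041 with DMSO, and 71.5% of their 1021 calls were higher.

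A candidate explanation is genomic DNA carried into the CBL0137 libraries, which would add reads evenly over the genome. If so, 398 olfactory receptor genes, a class silent in most cells, would have gained 265 reads. Their observed gain was -64.4 (upper 95% limit 16.7, counting error only), a ratio to the predicted gain of -0.244. This ratio ran from -0.559 to 0.0341 over the 4 pairings of a CBL0137 with a DMSO library. The class was not silent here, with 805 reads in the DMSO and 795 in the CBL0137 libraries. A fall in expressed receptors could mask a gain from DNA, so this test cannot decide. Of the 398 genes, 343 had 0 reads in the CBL0137 libraries where 230 were expected from DNA alone, so fewer had reads than predicted. Both predictions rest on annotated exon lengths, and the annotation used for counting is not given. Reads aligned to more than 1 place are counted in no gene, which was not allowed for. Genomic DNA therefore stays open as an explanation. Low abundance of lncRNA genes stays open for the direction of their calls: protein-coding genes matched on abundance had 68.3% higher calls (middle 95% of 1000 draws 65.7 to 70.9). The lncRNA share of 71.5% lies above that range, which met the criterion first written against this explanation, but its Wilson interval (68.7 to 74.2) overlaps the range, so the excess is not beyond its spread and the explanations cannot be told apart. The counts do not show whether the reads counted in no gene lay between genes or in introns. More RNA from either with CBL0137 and a difference in library preparation between the groups also stay open, untested.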

How the results depend on the processing

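The fits with the GC and gene span trend removed, alone or with the replicate block, and of protein-coding genes only were chosen after seeing the data. The counts of genes changed (5798), higher (3166) and lower (2632) stayed within 1.5 times under the other normalizations, DESeq2, both other filters on low counts, each library left out (5117 to 5549 changed, 2699 to 2974 higher, 2418 to 2655 lower) and the added fits. They moved further with no fold limit (10722 changed, 5347 higher, 5375 lower), a fold above 2 (3206, 1988 and 1218) and a test against a fold of 1.5 (3670, 1991 and 1679), each by construction of the threshold. With limma on FPKM they were 3239, 1767 and 1472. Of the 5798 calls that fit shared 2531 in the same direction and 3 in the opposite direction, and DESeq2 shared 4473. The FPKM fit held 12622 of the 17374 tested genes, so calls on the others could not be shared. The added 1 also draws differences at low FPKM under the fold limit. How much of the gap these account for was not tested, nor was the cause for DESeq2. Replicate numbers did not pair the samples (correlation of same-numbered deviations 0.0196): a replicate block gave 5741 calls (3129 higher, 2612 lower), 5719 of them shared with the fit without it, changed no named gene's or list's call and left 9 lists called. With the trend removed as well it gave 5507 calls. Removing the trend alone gave 5546 calls, 4813 shared.

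Of 23 lists, 9 were called with camera, 9 to 10 with a library left out, 8 with the trend removed, 0 with an estimated correlation and 15 with fry, which does not compare a list with other genes. The direction of lists that were not called turned in these cases, and the cause was not tested. For apoptosis-promoting genes the adjusted p was 0.965 with library size alone, 0.982 with the stricter filter, 0.149 with fry and 0.814 without CBL0137 replicate 1; across the fits with a library left out it ran from 0.606 to 0.962, and the other 3 kept the direction. For EWSR1-FLI1 repressed genes it was 0.702 with fry and 0.962 without DMSO replicate 2; the other 3 fits with a library left out kept the direction (range 0.624 to 0.962). It was 0.188 for interferon-stimulated genes with fry, and 0.798 for G2/M and 0.627 for immediate early genes with the trend removed. Of 830 recomputed values of 64 named genes, 819 kept direction and side of the threshold, 4 lost the call, 4 gained it and 3 turned: FLI1 in 2 of the 4 fits with a library left out (-0.010 to 0.049 across the 4) and NKX2-2 (-0.044 with the trend removed). Apart from the fixed set, the named genes were picked for a large fold or small p in these data, which favours such stability. It does not stand for all calls: with FPKM 61 named genes kept direction and side, but 43.65% of the 5798 calls were shared. That percentage counts calls on genes outside the FPKM fit as not shared, so it overstates the disagreement. Variants for a table of FPKM alone were not run, as counts were given. In the simulation, drawn at this depth and spread but with few changed genes, 65.7% of genes changed 1.5-fold reached an adjusted p under 0.05. That share does not carry over to the real data, where many more genes differed. How far depth limits low genes was not tested.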

Other observations

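The 5 gene lists described first, and the fit with the GC and gene span trend removed, were chosen after the data were seen; the other tests in this part were set before their values were seen, on patterns noticed in the data. Genes of cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, were lower with CBL0137: 15 of 20 fell, 0 rose and 5 were not called (median log2 fold change -1.08, camera adjusted p = 3.7e-06, and adjusted p = 0.400 with an estimated correlation). FARSB, a subunit gene of the phenylalanine enzyme, fell from 294 ± 6.97 to 33.6 ± 6.80 CPM (SD, n = 2), a log2 fold change of -3.13, while FARSA, the gene of its partner subunit, was at -0.33 and not called. GARS1 (-1.71) and MARS1 (-1.54) fell, and HARS1 (0.55) and QARS1 (0.11) were not called, though HARS1 was with upper-quartile factors (0.62) and library size alone (0.71). Translation initiation and elongation factor genes had 9 of 33 lower (6 with upper-quartile factors or the GC and span trend removed, and 4 with library size alone, where the median was -0.20) and 0 higher (median -0.36, camera adjusted p = 2.4e-05, and adjusted p = 0.400 with an estimated correlation), with EIF2S2 (-0.95) among those that fell.

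Lysosomal genes went the other way, with 19 of 43 higher, 4 lower (2 with FPKM) and 20 not called (median 0.46, camera adjusted p = 0.0011, and adjusted p = 0.284 with an estimated correlation). The cathepsin gene CTSF rose from 8.93 ± 0.366 to 67.0 ± 1.36 CPM (SD, n = 2), a log2 fold change of 2.91, and the sulfamidase gene SGSH (1.97), the sialidase gene NEU1 (1.58) and the acid glucosidase gene GAA (1.31) rose. Among those that fell were CTSO (-1.58) and LIPA (-1.42). Proteasome subunit genes had 3 of 31 lower, PSMD14 (-0.89), PSMA7 (-0.86) and PSMC3 (-0.61), and 0 higher (median -0.08, camera adjusted p = 0.426). PSMC3 was not called with upper-quartile factors (-0.55), library size alone (-0.46) or FPKM (-0.52), nor without CBL0137 replicate 1 (-0.58). Of 13 mitochondrially encoded mRNAs, 0 were called by edgeR and the median was -0.0047 (camera adjusted p = 0.799), from MT-CO2 at -0.30 to MT-ND6 at 0.37. Under the scalings tried, the medians of the synthetase, translation factor and lysosomal lists kept their sign. That of the proteasome list turned with library size alone (0.08) and with FPKM or the trend removed (0.01 each). That of the mitochondrial mRNAs turned with library size alone (0.15), upper-quartile factors or FPKM (0.06 each), the stricter filter (0.01) and without DMSO replicate 1 (0.02) or CBL0137 replicate 1 (0.03).

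The direction of change followed GC content and gene span across genes, which are not independent replicates (Spearman's rho 0.24 with GC and -0.15 with log2 span over 17252 genes). Gene span as the whole cause is argued against, since within 5 bins of span the rho with GC was 0.134 or more. GC variation of the size seen between replicates is argued against too, as the larger replicate slope on GC was 0.144 of the slope between groups (0.24 on the log2 scale per 10 points of GC). A GC bias as the whole cause stays open, with rho between span and change within GC bins from -0.0892 to -0.0494, the latter nearest to 0. A bias of library preparation that differed between the groups and an effect of CBL0137 on GC-rich or short genes cannot be told apart in this design, and with the trend removed 4813 of the 5798 calls were shared.

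Ribosomal protein genes lost 20439 CPM in sum, from 61895 ± 2906 with DMSO to 41456 ± 703 with CBL0137 (SD, n = 2). The median log2 fold change of -0.52 lay below -0.419, the 2.5th percentile of 10000 matched lists, whose own median was -0.27. This met the criterion written against GC content, span and abundance as the whole cause. The matched lists were drawn gene by gene, however, while the ribosomal protein list had an estimated correlation between genes of 0.627. Their range is too narrow for such a list, so the comparison cannot exclude this explanation. Abundance was matched imperfectly, with a median log2 CPM of 9.18 in the list and 8.42 in its neighbours. A move of uniquely aligned reads to ribosomal protein pseudogenes is argued against, as 1596 pseudogenes gained -1.34% of the CPM lost. Their sum was 794 CPM with DMSO and 521 CPM with CBL0137. Reads aligned to more than 1 place are counted in no gene, so a move of reads to that class was not tested. Lower abundance of these mRNAs with CBL0137 may remain as a hypothesis found and tested on the same libraries, beside their GC content, span and abundance. A difference in preparation between the groups also remains and was not tested.

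The deposited FPKM and counts differed for some genes: of 8273 genes with a mean FPKM of at least 5, 60 had replicates over 2-fold apart in FPKM, and 51 of these had CPM less than 1.2-fold apart. RPL7 had FPKM of 360 and 1115 in CBL0137 replicates 1 and 2 against counts of 41713 and 43609.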
